A study of Homo sapiens with 26 samples.

How the data were processed

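Human sperm chromatin was digested with 10 to 160 U of MNase per the labels' protocols, from 40000000 sperm for the nucleosome preparations, whose DNA of 140–155 bp was taken from a gel. For ChIP, adapter-ligated fragments of 220–280 bp were taken, and the washes held 250 mM NaCl and 200 mM LiCl. Each immunoprecipitation was done 3 times and pooled per the labels. The 26 lanes fell into 7 groups by their labels: H2A.Z ChIP (1 lane), H3K4me3 ChIP (3), H3K27me3 ChIP (2), nucleosomes of the single donor (7), nucleosomes of the donor pool (6), input of the single donor (3) and input of the donor pool (4). Per the series design the donor pool combined 4 donors, with about 6000000 nucleosome reads each. The 6 lanes it assigns to the donor-pool nucleosome list are labelled with 3 donors, none of them the single donor, and whether reads of the single donor also entered that list is not settled by the sources used here. The input groups have no list of their own and entered only as a control.

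Per the deposited description of the lists, the authors aligned reads to hg18 with the ELAND extended aligner, kept alignments with a score above 13 and removed reads in satellite repeats. They compared ChIP or nucleosome reads with control reads in windows of 300 bp with the USeq package, by a binomial p-value turned into a false discovery rate with Storey's q-value method, and joined the windows past a threshold into regions. The versions of these tools were not given in the sources used here. The thresholds were 0.1 for H2A.Z, 0.0001 for H3K4me3 and H3K27me3, and 0.01 for both nucleosome lists. The deposited description names input as the control. The series design instead states that the ChIP reads were compared with donor-pool nucleosome reads, with the single donor reduced to 5000000 reads, and the nucleosome reads with 20000000 input reads. The files do not settle which control the ChIP lists used, and the overlap of ChIP with nucleosome regions depends on it. Satellite filtering and the alignment filter thin out reads in repeats, so regions there are undercounted. Each list was called once on pooled lanes.

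The deposited counts are whole numbers of treatment and control reads in the best window of each region. The deposited score columns hold a normalised difference and the p-value and q-value of the best window as −10 log10. The normalised difference of each best window was checked to equal the difference of the 2 read counts divided by the square root of their sum. The score used for ranking is this normalised difference of the authors, and it was compared only by rank within a list. Coordinates are printed as listed, since the deposited description does not say whether starts count from 0 or 1. Regions on the Y chromosome and mitochondrial DNA were left out throughout.

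Overlap was counted from 1 bp, and compared with 1000 random placements of the tested list, each region staying on its chromosome within the span the lists cover. Random placement does not keep mappability, base composition or uneven density along a chromosome, so the folds also count what lists share in these. Shares have 95% Wilson intervals and ratios of reads have exact binomial intervals. The counting interval of a region's reads is conditional on its having been listed. PCR reads are not independent molecules, so intervals cover counting error only. Spreads over the 22 autosomes describe the genome, not replicate samples, and no p-value across samples was computed. Clustering was the share of regions with another region of the same list within 10 kb, against 1000 placements. Densities are per Mb of the span from the first to the last listed region of a chromosome, over all lists. Alternatives set before the data were examined were an overlap of at least 50% of the shorter region, the highest-scoring 50% of each list, circular shifts of a list, autosomes alone, merged regions and clustering distances of 1 and 100 kb. The overlap count was tested on simulated H3K4me3 lists of 34911 regions against the deposited H3K27me3 list. With 10% and 20% of the regions planted, 9.86% and 19.8% were recovered, and with none planted 81 of 100 placements reached the simulated overlap. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

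The rule for regions named in the text was set before the data were examined. It took the 5 highest-scoring regions of each list and the 3 windows of 100 kb with the most regions. It did not say how to break ties, which went to the larger covered length. Regions of the single donor are named only where a donor-pool region overlaps them, and their density on X is not reported. The longest runs of regions and the chromosomes with extreme densities were named after their values were seen. No gene annotation on hg18 was used here and coordinates were not converted between builds, so no gene names are given, and the planned counts of promoters over 12 gene lists fixed in advance were not run.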

Results

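Mature human sperm package most of their DNA with protamines, and a small part of the genome keeps histones. The series mapped that part by sequencing. Nucleosomes released with micrococcal nuclease (MNase), an enzyme that digests the DNA between nucleosomes, were sequenced in 7 lanes from a single donor and in 6 lanes labelled with 3 other donors, the lanes that the series assigns to its donor-pool list. The series design describes that pool as 4 donors, and combines the single donor's reads with those of the others where it names the pool as a control. Chromatin of the donor pool was immunoprecipitated (ChIP) for the histone variant H2A.Z in 1 lane, for H3K4me3 in 3 lanes and for H3K27me3 in 2 lanes. H3K4me3 is a histone mark typical of active or poised promoters, and H3K27me3 is the mark placed by Polycomb repressive complexes. Input DNA was sequenced in 3 lanes from the single donor and in 4 lanes from the donor pool, which makes 26 lanes in all. The processed data were 5 lists of enriched regions on the human genome build hg18, each made from all lanes of a group together. No value therefore has a replicate error, and the intervals given cover counting error only. Read totals per lane were not given in the sources used here, so depth is described by the reads in the best window of each region.

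The nucleosome lists held similar numbers of regions for the donor pool and the single donor, while the H3K4me3 and H3K27me3 lists were longer and the H2A.Z list was very short. The donor pool gave 25094 nucleosome regions with a median width of 582 bp, covering 18.3 Mb. The single donor gave 25558 nucleosome regions with a median width of 424 bp, covering 13.7 Mb. H3K4me3 gave 34911 regions covering 44.0 Mb and H3K27me3 gave 38334 regions covering 34.8 Mb. H2A.Z gave 116 regions covering 0.0695 Mb. The thresholds of the lists differed, with a false discovery rate of 0.1 for H2A.Z, 0.01 for both nucleosome lists and 0.0001 for both H3 marks, so the numbers of regions do not measure the amount of each mark.

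The H3K4me3 regions were the widest on average, with a median of 718 bp (95% interval 707 to 729) against 636 bp (631 to 641) for H3K27me3. Of the H3K4me3 regions, 17.9% were wider than 2 kb, and the widest reached 22400 bp. Of the H3K27me3 regions, 7.36% were wider than 2 kb, and the widest reached 11120 bp. In the best window, the median H3K4me3 region held 34 ChIP reads against 2 control reads, and the median H3K27me3 region held 28 against 1. The median donor-pool nucleosome region held 24 reads against 2 control reads, and the median single-donor region 27 against 4. The median H2A.Z region held 26 reads against 0, and 63.8% of H2A.Z regions had no control read in the best window. The best window was chosen for its enrichment, so these reads describe the listed regions and overstate typical enrichment.

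How far the nucleosome regions of the single donor recurred in the donor pool was the first comparison. Of the 25558 single-donor regions, 12745 overlapped a donor-pool region by at least 1 bp, a share of 49.9% (95% Wilson interval 49.3 to 50.5). In the other direction, 48.8% of the donor-pool regions overlapped a single-donor region. The share was similar along the genome, with a mean over the autosomes of 50.3% ± 3.90 (SD, n = 22 chromosomes), a minimum of 44.1% on chromosome 11 and a maximum of 58.5% on chromosome 16. Random placement of the single-donor regions within their chromosomes gave a mean of 328.2 overlapping regions, so the observed overlap was 38.8 times the placed mean, and 0 of 1000 placements reached it. Placement was even along a chromosome, while 25.0% of donor-pool and 20.6% of single-donor regions lay in the 6.98% of the span nearest the chromosome ends. The fold therefore also counts uneven density that the lists share, and does not by itself measure retention at the same sites. The series design counts 4 donors in the pool but assigns lanes of 3 to the donor-pool nucleosome list, so it is open whether the lists shared reads of the single donor. With only the highest-scoring 50% of each list, the share was 48.2% and the placed share fell from 1.28% to 0.830%, which made the overlap 58.0 times the placed mean.

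Donor-pool nucleosome regions with high scores recurred more often in the single donor than those with low scores. Of the donor-pool regions in the highest score quartile, 74.8% (73.7 to 75.9) overlapped a single-donor region, followed by 54.9%, 38.2% and 27.2% (26.1 to 28.3) in the following quartiles. The median width fell in the same order, from 1018 bp to 370 bp, and wider regions overlap more by chance. Across the 12745 shared regions, the authors' scores had a Spearman correlation of 0.22 (95% bootstrap interval over regions 0.21 to 0.24). This correlation is across regions, which are not independent replicates. The highest-scoring donor-pool nucleosome region lay on chromosome 16 at 33867013–33867383, with 251 reads against 26 control reads, a ratio of 9.65 (exact binomial interval 6.43 to 15.1), and it overlapped single-donor, H3K4me3 and H2A.Z regions. The next lay on chromosome 2 at 132730180–132732847, with 221 reads against 21, and on chromosome 16 at 33201376–33202531, with 173 against 18. The fourth was on chromosome 10 at 127574377–127575622, with 162 reads against 15, and overlapped both H3 marks. The fifth was on chromosome 12 at 131853710–131854327, with 154 reads against 13. All 5 overlapped a single-donor region. Among the highest-scoring single-donor regions shared with the donor pool were chromosome 20 at 26136546–26137735, with 900 reads against 114, chromosome 8 at 70764907–70765399, with 720 against 194, and 2 regions on chromosome 2, at 132741759–132742844 with 636 reads, 5.17 times the control, and at 132739237–132739697 with 362 against 85. The chromosome 8 ratio was 3.71 (3.16 to 4.37). Control reads of the named regions were far above the list medians of 2 (donor pool) and 4 (single donor). At a given ratio of reads to control the score rises with depth, so a high score can reflect depth as well as enrichment.

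**Figure D1:**
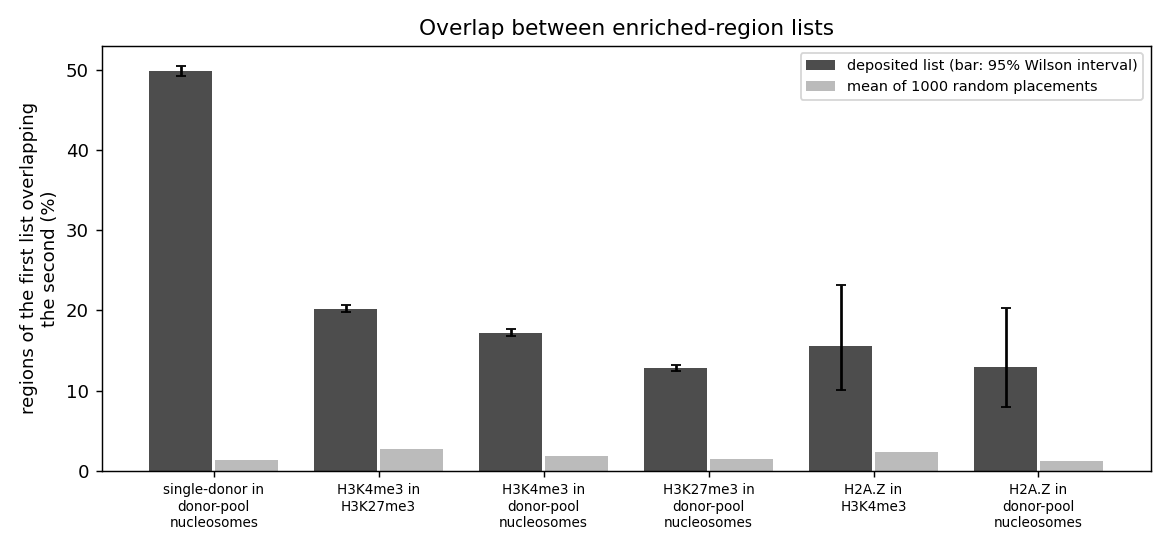
Share of the regions of a list that overlapped another list by at least 1 bp (y axis, percent) for the 6 list pairs on the x axis. Dark bars are the deposited lists with 95% Wilson intervals, and light bars are the means of 1000 random placements. The share was 49.9% for single-donor regions in donor-pool nucleosomes, and the dark bar stood above the light bar in all 6 pairs.

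H3K4me3 and H3K27me3 mark opposite transcriptional states in most differentiated cells and occur together at bivalent promoters of stem cells, and the series asked where each lies in sperm. Of the 34911 H3K4me3 regions, 7055 overlapped an H3K27me3 region, a share of 20.2% (19.8 to 20.6). In the other direction, 20.0% of the H3K27me3 regions overlapped an H3K4me3 region. Random placement gave a mean of 943.0 overlapping regions, so the observed overlap was 7.48 times the placed mean, and 0 of 1000 placements reached it. By autosome the share averaged 19.6% ± 3.86 (SD, n = 22 chromosomes), with 27.2% on chromosome 6 and 12.6% on chromosome 22. The series design states that both marks were tested against the same donor-pool nucleosome reads. A calculation without ChIP enrichment assumed even, independent counts for both marks and the control, at 5 times the mean density of 20000000 reads. It gave 1.30 windows called in both lists. Uneven control depth along the genome was not modelled, so this value does not measure what a shared control adds. The control lanes could not be split, so part of the excess over random placement may come from the shared control.

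In each H3 list, regions in the highest score quartile overlapped the other mark more often than those in the lowest, and they were also wider. Of the H3K27me3 regions in the highest score quartile, 34.7% overlapped an H3K4me3 region, against 10.4% in the lowest. Of the H3K4me3 regions, 26.3% in the highest quartile overlapped an H3K27me3 region, against 16.0% in the lowest. Median widths fell over the quartiles from 1394 to 372 bp for H3K27me3 and from 2369 to 372 bp for H3K4me3. When both lists were reduced to their highest-scoring 50%, the share of H3K4me3 regions overlapping H3K27me3 was 17.4%, against 20.2% for the full lists. The placed share fell from 2.70% to 2.06%, and the overlap was then 8.47 times the placed mean. The best windows of the marks often coincided: the density of H3K27me3 best windows was 279 per Mb within 200 bp of an H3K4me3 best window, against 16.9 per Mb at 50000 to 100000 bp. Across the 7055 shared regions the scores had a Spearman correlation of 0.13 (0.10 to 0.16). All 5 of the highest-scoring H3K4me3 regions overlapped H3K27me3. They lay on chromosome 6 at 90650387–90655431, with 442 reads against 17 and a ratio of 26.0 (16.1 to 45.0), on chromosome 1 at 17069714–17074897 and chromosome 15 at 62901634–62907236, each with 369 reads against 9, on chromosome 16 at 6562424–6566556, with 371 against 14, and on chromosome 17 at 38734606–38737279, with 343 against 10. The highest-scoring H3K27me3 region, on chromosome 4 at 77025920–77026622, had 222 reads against 19 and overlapped H3K4me3 and H2A.Z. The other 4 were on chromosome 2 at 132752891–132754186 with 151 reads against 1, chromosome 21 at 26149768–26150371 with 155 against 5, chromosome 1 at 143748288–143752964 with 148 against 4, and chromosome 2 at 91141691–91143489 with 195 against 23. All of these also overlapped H3K4me3.

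Whether the marked regions lay at the nucleosome regions of the donor pool was compared next. Of the H3K4me3 regions, 6018 overlapped a donor-pool nucleosome region, a share of 17.2% (16.8 to 17.6) and 9.61 times the placed mean of 625.9. Of the H3K27me3 regions, 4904 did so, a share of 12.8% (12.5 to 13.1) and 9.07 times the placed mean of 540.8. None of 1000 placements reached either overlap. The share was higher for H3K4me3 than for H3K27me3 in 22 of 22 autosomes, by 4.68 percentage points ± 1.99 (SD, n = 22 chromosomes), and the H3K4me3 regions were also wider. In the single donor's nucleosome list the shares were 11.0% for H3K4me3, 6.85 times the placed mean, and 9.09% for H3K27me3, 7.17 times the placed mean, so the order of the folds was the other way round.

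Most overlaps of H3K27me3 regions with nucleosome regions covered less than 50% of the shorter region. When at least 50% of the shorter region had to be covered, 1024 H3K27me3 regions overlapped donor-pool nucleosomes, a share of 2.67% and 2.81 times the placed mean. The same requirement left 2754 H3K4me3 regions, a share of 7.89% and 6.03 times the placed mean. For the single donor's nucleosomes it left 4.03% of the H3K27me3 regions, 4.59 times the placed mean, and 6.93% of the H3K4me3 regions, 5.73 times. The density of donor-pool nucleosome best windows was 8.22 per Mb within 200 bp of an H3K27me3 best window, 119 per Mb at 600 to 800 bp, and 10.6 per Mb at 50000 to 100000 bp. Around H3K4me3 best windows it was 29.4 per Mb within 200 bp, 119 per Mb at 400 to 600 bp and 12.2 per Mb at 50000 to 100000 bp, so the centre was above the distant level for H3K4me3 and below it for H3K27me3. Per the series design, the donor-pool nucleosome reads were themselves the control for both marks, while the description with the lists names input as the control. With the highest-scoring 50% of each list, 13.4% of H3K27me3 regions overlapped nucleosomes, and a placed share of 0.973% instead of 1.41% made this 13.7 times the placed mean, against 11.1 times for H3K4me3, so the order of the folds of the marks depended on the setting.

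**Figure D2:**
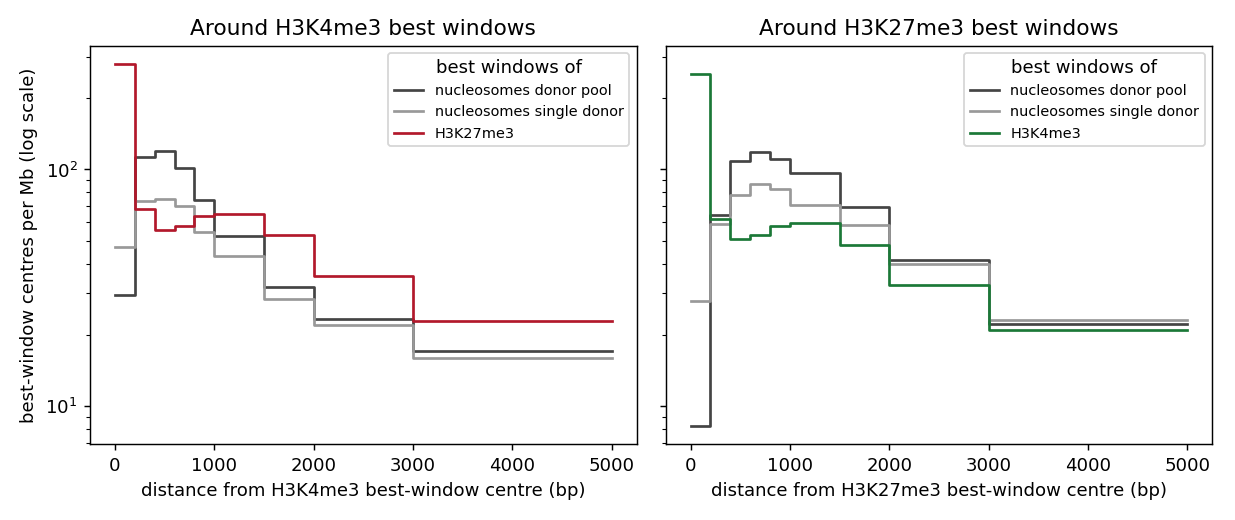
Density of best-window centres (y axis, per Mb, log scale) by distance in bp (x axis) from the best-window centres of H3K4me3 regions (left) and H3K27me3 regions (right). Lines are the donor-pool nucleosome, single-donor nucleosome and other H3 mark lists. Around H3K27me3 the donor-pool nucleosome line rose from 8.22 per Mb within 200 bp to 119 per Mb at 600 to 800 bp.

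Regions of an H3 list that overlapped the other H3 list lay at nucleosome regions more often than those that did not. Of the H3K4me3 regions that overlapped H3K27me3, 33.0% (31.9 to 34.1) overlapped a donor-pool nucleosome region, against 13.3% (12.9 to 13.7) of the H3K4me3 regions without it. Of the H3K27me3 regions that overlapped H3K4me3, 22.4% (21.5 to 23.4) did so, against 10.4% (10.1 to 10.7) of those without it. Regions with both marks were wider, with medians of 839 against 687 bp for H3K4me3 and 977 against 597 bp for H3K27me3. Within the narrowest quartile of H3K4me3 regions the shares were 20.3% with and 8.06% without H3K27me3, and within the widest quartile 46.4% and 20.4%. Within the narrowest quartile of H3K27me3 regions the shares were 10.9% with and 4.27% without H3K4me3, and within the widest quartile 30.8% and 20.3%. The intervals did not overlap in any of the 4 width quartiles of either mark, but they treat neighbouring regions as independent. Score was not held fixed. Regions with both marks had higher median scores, 5.57 against 5.11 for H3K4me3 and 5.43 against 4.80 for H3K27me3. From the highest to the lowest score quartile the share at nucleosome regions fell from 28.5% to 8.82% for H3K4me3 and from 24.7% to 3.78% for H3K27me3. Part of the difference may therefore go with score.

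Most donor-pool nucleosome regions overlapped no listed region of either mark, and neither mark is used below in this sense. Absence from a list is not absence of the mark. Per the series design, donor-pool nucleosome reads were the control for both marks, while the description with the lists names input. If they were the control, windows rich in them would be called less often. The regions with neither mark may then be overcounted, and the comparison of the classes affected. Of the 25094 regions, 16812 overlapped no H3K4me3 or H3K27me3 region, 3942 overlapped H3K4me3 alone, 2720 overlapped H3K27me3 alone and 1620 overlapped both. Independent overlaps of the marks with these regions would have given 962 regions with both. The regions with neither mark recurred in the single donor in 45.8% (45.0 to 46.5) of cases, against 52.0% with H3K4me3 alone, 58.2% with H3K27me3 alone and 56.3% (53.9 to 58.7) with both. Marked regions had higher scores, and these differences were smaller within score quartiles. For H3K4me3 alone, the intervals overlapped those of regions with neither mark in all 4 quartiles. For H3K27me3 alone, the share was higher in the highest quartile, at 78.2% (75.4 to 80.7) against 72.9% (71.4 to 74.4), and in the next, at 63.6% (60.0 to 66.9) against 54.1% (52.5 to 55.7), and the intervals overlapped in the lower 2. For both marks it was higher in the highest quartile alone, at 80.0% (76.7 to 82.9).

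The H2A.Z list was short and overlapped little of the other lists in absolute terms. Of the 116 H2A.Z regions, 18 overlapped H3K4me3, a share of 15.5% (10.0 to 23.2) and 6.82 times the placed mean. Overlaps with donor-pool nucleosome regions numbered 15, a share of 12.9% (8.00 to 20.2) and 10.6 times the placed mean, and 16 H2A.Z regions overlapped H3K27me3, 7.58 times the placed mean. In all, 33 H2A.Z regions (28.4%) overlapped any of these lists, and 0 of 1000 placements reached any of these overlaps with a single list. The intervals treat H2A.Z regions as independent, although 55.2% lay within 10 kb of another. The windows at 33.8–33.9 Mb of chromosome 16 and 132.7–132.8 Mb of chromosome 2 held 6 and 5 H2A.Z regions and many regions of the other lists. The share of the overlaps that came from these windows was not counted. The highest-scoring H2A.Z regions were on chromosome 9 at 42405730–42406168 with 182 reads against 0, chromosome 7 at 56405156–56406909 with 1 control read, chromosome 2 at 94838730–94838984 with 115 against 0, chromosome 10 at 98551233–98551616 with 116 against 10, and chromosome 1 at 120345289–120345742 with 78 against 1. Of these 5, the region on chromosome 10 overlapped H3K4me3. The list came from 1 lane at the loosest threshold, and with the highest-scoring 50% of each list the H3K4me3 overlap was 13.3 times the placed mean, with 12 of 58 regions, and the H3K27me3 overlap 14.4 times, with 11 of 58.

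All 5 lists were clustered along the chromosomes. Within 10 kb of another region of the same list lay 64.4% of H3K27me3 regions, against 26.3% after random placement, and 64.0% of H3K4me3 regions, against 24.9%. The shares were 45.8% for donor-pool nucleosomes, against 20.1% placed, 46.6% for the single donor, against 18.9%, and 55.2% for H2A.Z, against 0.162%. None of the 1000 placements reached any of these shares. Many neighbours were very close: within 1 kb of another lay 43.3% of H3K4me3 regions, against 5.62% placed, and 38.6% of H3K27me3 regions, against 5.21%. Such neighbours may be parts of 1 broader domain listed separately, which was not tested. Runs of at least 20 regions spaced by less than 10 kb numbered 10 for H3K27me3, 20 for donor-pool nucleosomes and 0 for H3K4me3. The longest H3K27me3 run held 47 regions on chromosome 6 at 27247233–27386515, and the longest donor-pool nucleosome run held 34 regions on chromosome 16 at 1015084–1121676. At 100 kb, 86.2% of donor-pool nucleosome regions had a neighbour, against 82.8% placed, so that distance separated these lists little from random placement.

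The densest 100 kb windows of the H3K27me3 list also held many nucleosome and H3K4me3 regions. The window at 27.1–27.2 Mb of chromosome 7 held 36 H3K27me3 regions covering 51.8 kb, with 20 donor-pool nucleosome and 9 H3K4me3 regions. The window at 140.7–140.8 Mb of chromosome 5 held 33 H3K27me3, 14 H3K4me3 and 5 nucleosome regions, and the window at 52.6–52.7 Mb of chromosome 12 held 33, 6 and 13. Over the 190 windows with at least 10 H3K27me3 regions, the mean number of donor-pool nucleosome regions was 4.14 ± 3.46 (SD over windows), against a genome mean of 0.855, and the mean number of H3K4me3 regions was 3.74 ± 3.05, against 1.19. The densest H3K4me3 windows were at 191.3–191.4 Mb of chromosome 1 with 18 regions, 157.0–157.1 Mb of chromosome 5 with 16 and 5.4–5.5 Mb of chromosome 20 with 16, and each held at most 1 H3K27me3 region. The last 2 were among 5 windows tied at 16 regions. Another of these tied windows, at 33.8–33.9 Mb of chromosome 16, held 13 H3K27me3 regions. Over all 113 windows with at least 10 H3K4me3 regions, the mean number of H3K27me3 regions was instead 3.65 ± 6.10 (SD over windows), above the genome mean of 1.31. The densest nucleosome windows lay at 1.0–1.1 Mb of chromosomes 16, 19 and 1, with 27, 27 and 26 donor-pool regions. They held 0, 2 and 1 H3K4me3 regions and 0 H3K27me3 regions. The single donor's list had 30 regions in the chromosome 16 window. H2A.Z was densest at 33.8–33.9 Mb of chromosome 16 with 6 regions, 48.9–49.0 Mb of chromosome 4 with 6, and 132.7–132.8 Mb of chromosome 2 with 5. The chromosome 16 window also held 8 donor-pool nucleosome, 16 H3K4me3 and 13 H3K27me3 regions. In the same order the chromosome 2 window held 8, 12 and 14, and the chromosome 4 window 2, 0 and 0.

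**Figure D3:**
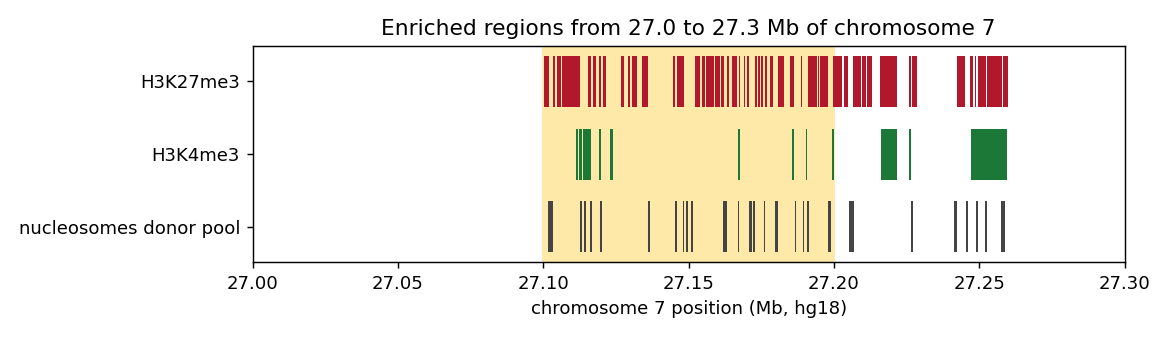
Map of the donor-pool nucleosome, H3K4me3 and H3K27me3 regions from 27.0 to 27.3 Mb of chromosome 7 (x axis, hg18 position in Mb), with 1 row per list and blocks drawn to scale. The shaded window at 27.1–27.2 Mb held 36 H3K27me3, 9 H3K4me3 and 20 nucleosome regions.

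Chromosomes differed in density. Donor-pool nucleosomes and H3K4me3 had the same 3 densest autosomes, and H3K27me3 had others. Donor-pool nucleosome regions were densest on chromosome 19, at 30.3 per Mb, followed by 19.2 on chromosome 22 and 18.1 on chromosome 17, against an autosomal mean of 10.3 ± 5.74 (SD, n = 22 chromosomes). H3K4me3 regions were also densest on chromosome 19, at 17.7 per Mb, with 17.2 on chromosome 22 and 16.9 on chromosome 17, against a mean of 13.0 ± 2.21. H3K27me3 regions were densest on chromosome 6, at 17.2 per Mb, and sparsest among the autosomes on chromosome 22, at 9.69 per Mb, against a mean of 13.9 ± 1.95. The X chromosome held few regions of 3 donor-pool lists, with 189 nucleosome, 22 H3K4me3 and 4 H3K27me3 regions. Of the H2A.Z list it held 3 regions, a density of 49.0% of the autosomal one with an exact Poisson interval of 10.1 to 143%, so no depletion was detectable.

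**Figure D4:**
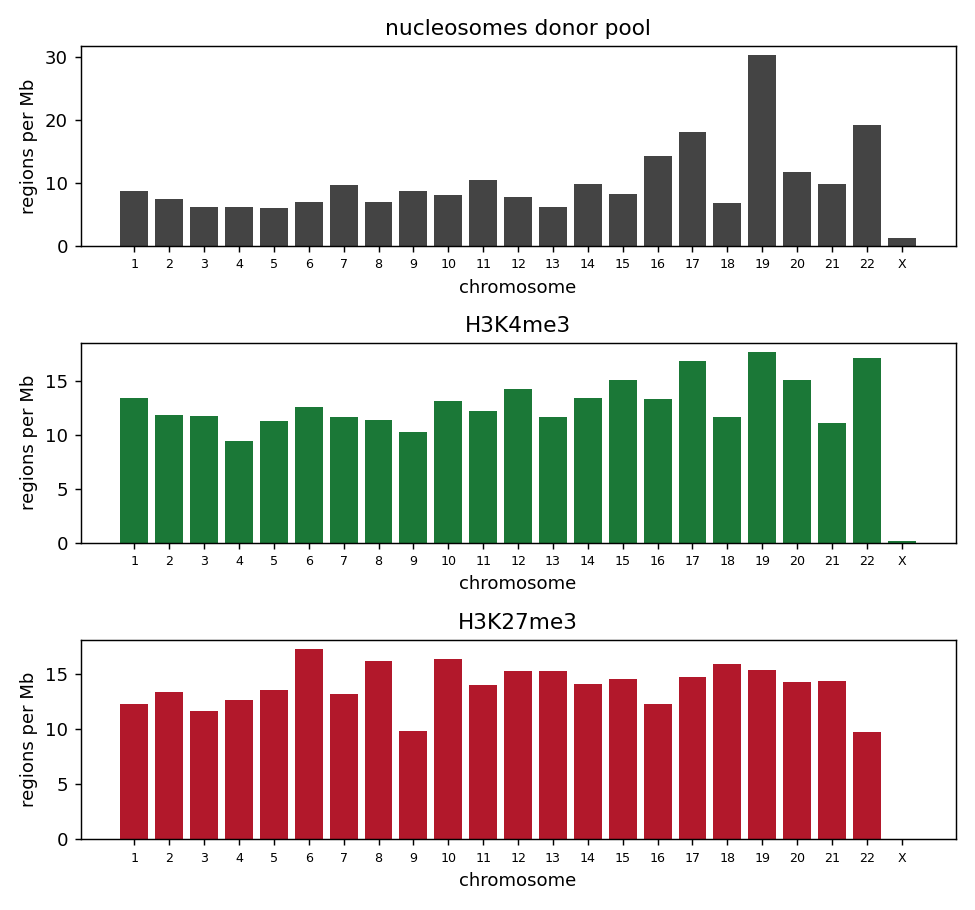
Regions per Mb (y axis) on each autosome and X (x axis) for the donor-pool nucleosome, H3K4me3 and H3K27me3 lists, with 1 bar per chromosome and no error, since each list is a single pooled call. Nucleosome regions reached 30.3 per Mb on chromosome 19, and H3K27me3 regions were sparsest among the autosomes on chromosome 22, at 9.69 per Mb.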

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

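Placement within 1 Mb bins that held a listed region was chosen after seeing the data. So was the removal of regions within 1 Mb of the largest region-free interval of each chromosome. The other settings were chosen before, except as stated next. The score quartiles of marked nucleosome regions were also chosen after seeing the data. The same holds for all settings for H2A.Z with H3K27me3 and for both H3 marks with single-donor nucleosomes. The comparisons by presence of the other mark, the other score and width quartiles and the distance profiles were not in the plan set before. Also outside it were the windows with at least 10 regions, the difference between the H3 marks by autosome and the shared-control calculation. In the 9 overlap comparisons, all 54 alternatives kept the overlap above the mean placement, with 0 of 1000 placements reaching it and folds from 2.81 (H3K27me3 with donor-pool nucleosomes at 50% of the shorter region) to 58.0 (single donor with donor pool, highest-scoring 50%). In the 15 alternatives of the clustering, 0 of the placements reached the observed share. At 100 kb the share was close to the placed one except for H2A.Z. The rank correlation of the nucleosome lists was 0.23 with the stricter overlap and 0.22 on autosomes. Taking the highest-scoring 50% changed list sizes by construction, to 12547 regions for the donor pool, 12779 for the single donor, 17455 for H3K4me3, 19167 for H3K27me3 and 58 for H2A.Z. Median widths were then 841, 555, 1459, 1083 and 569 bp in the same order. The covered length was then 8.65 Mb for the single donor and 0.0451 Mb for H2A.Z. Merging overlapping or touching regions changed no list. No paired analysis was possible because each list was made from pooled lanes, and lane numbers do not pair samples. For the same reason no lane could be left out. The planned promoter counts and their alternatives were not run, since no hg18 annotation was used here. The H2A.Z comparisons rest on 116 regions from 1 lane, which sets their wide intervals.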

Other observations

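All tests in this part were chosen after the result was seen. Donor-pool nucleosome regions were concentrated toward chromosome ends. Within 5 Mb of the outermost listed positions lay 25.0% (95% Wilson interval 24.5 to 25.6) of the donor-pool nucleosome regions, where 6.98% of the listed span lies, and 20.6% of the single-donor regions. The 6.98% leaves out the start of chromosomes 13, 14, 15, 21 and 22, where the largest region-free interval begins at position 0. The shares were 8.00% (7.72 to 8.29) for H3K4me3 and 9.16% (8.87 to 9.45) for H3K27me3. The 262 windows of 100 kb with at least 10 donor-pool nucleosome regions held on average 1.76 ± 2.32 (SD over windows) H3K4me3 regions and 2.15 ± 4.59 H3K27me3 regions, and 48.5% of them held any H3K27me3 region. The 113 windows with at least 10 H3K4me3 regions held 2.54 ± 2.79 donor-pool nucleosome regions.

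The X chromosome held few regions of 3 donor-pool lists relative to the autosomes, while for H2A.Z, at 49.0% (10.1 to 143), no depletion was detectable. Per Mb, its density was 1.16% (exact Poisson interval 0.729 to 1.76) of the autosomal density for H3K4me3, 0.193% (0.0525 to 0.493) for H3K27me3 and 14.0% (12.1 to 16.1) for donor-pool nucleosomes. X is at a lower dose than the autosomes in a mixed population of sperm, and this was tested by reducing the reads of autosomal best windows to 50% and counting those still past each list's weakest p-value, times the density of the sparsest autosome. This gave 32.0%, 18.5% and 24.9% of the autosomal density, above the observed values, which argues against a lower dose as the whole cause if reads scale with dose. The repeat content of X, the alignment filter and a real difference between X and the autosomes may add to it and were not tested.

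Nucleosome windows were less dense at the centres of the best windows of both marks than in their flanks. Only the donor pool around H3K27me3 fell below the density at 50000 to 100000 bp (8.22 against 10.6 per Mb), and the other centres lay above it (29.4 against 12.2 for the donor pool around H3K4me3, and in the single donor 27.7 against 10.8 around H3K27me3 and 46.8 against 11.5 around H3K4me3). The ratio of the density within 200 bp to that at 400 to 1000 bp was 0.0729 around H3K27me3 and 0.299 around H3K4me3 in the donor pool, against 0.337 and 0.704 in the single donor. If donor-pool nucleosome reads were the control for the ChIP lists, windows rich in them would be called less often, and the dip should be deeper in the donor pool. The donor-pool ratio divided by the single-donor ratio was 0.217 (bootstrap interval over chromosomes 0.178 to 0.255) around H3K27me3 and 0.425 (0.363 to 0.496) around H3K4me3, the direction that this control would give. Chromatin of the donor pool was also what was immunoprecipitated, so a real dip at marked sites could be deeper in its own nucleosome list. The comparison cannot tell this from an effect of the control. A dip remained in the single donor, part of whose reads were in the same control per the series design, so a real arrangement of nucleosomes beside marked sites may also contribute and was not tested.

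H2A.Z regions lay beside the largest interval without listed regions of each chromosome far more often than the other lists. These intervals measured 0.565 to 20.6 Mb and were not matched to an annotation. Within 1 Mb of them lay 36 of the 116 H2A.Z regions, 31.0% (23.3 to 39.9), on 10 chromosomes, against 0.896 to 1.25% of the other lists and 1.45% of the span. Chromosome 4 held 12 of them, and without it the share was 24.7% (24 of 97). Repeat copies collapsed in the assembly could collect reads and so raise the reads per best window there, but the values ran the other way: the median of H2A.Z plus control reads was 21 within 1 Mb and 30.5 farther away, a difference of -9.5 (bootstrap interval -16.5 to 0, two-sided permutation p = 0.00356, n = 36 and 80), and 29 of the 36 had no control read, against 45 of the 80. The test does not decide about collapsed copies, since the interval reached 0 and the farther regions may hold collapsed copies too. The few control reads do not decide it either, since a window with 20 H2A.Z reads could be listed with at most 1 control read. The permutation also treated the regions as independent, although 55.2% of H2A.Z regions lay within 10 kb of another, so its p-value may overstate the evidence. Stacks of duplicated reads from the 1 lane, the looser threshold and a real placement of H2A.Z there also stay open and were not tested.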
